A study of Rattus norvegicus with 15 samples.

How the data were processed

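Cell suspensions of rat digestive mucosa (Sprague Dawley males, per the labels) came from 5 segments, the stomach, duodenum, jejunum, ileum and colon, with 3 samples per segment and 15 in all. Per the series text, bowel segments were turned inside out, digested briefly with pronase and elutriated, and total RNA from 3 independent isolations was labelled with Cy3 or Cy5. The labels do not say whether the isolations came from separate animals, so the p-values measure only the spread between these isolations. Linear amplification labelling and Agilent whole-genome rat arrays were used, per the labels' protocols.

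Each scanner file held both channels of an array, and only the channel whose dye the labels gave to the sample was used for that sample. The deposited value table held intensities identical, within 0.02 on the log2 scale, to the processed signal of the labelled channel for 100.0% of 43628 spots in every sample. Per the file headers, that processed signal was an intensity with background subtracted and dyes normalised between the channels of an array by the Agilent scanner software. Division by the median over the data points and the comparisons in GeneSpring, named in the series text, were not part of the deposited intensities. Software versions differed between segments, per the file headers: 8.5.1.1 for the stomach, 9.5.1.1 for the duodenum, jejunum and ileum 1, 9.5.3.1 for ileum 2 and 3, and 10.1.1.1 for the colon. The limit above which the scanner software called a spot well above background also differed, with a background multiplier of 2.6 for the stomach and 13 for the duodenum, jejunum and ileum; the headers gave none for the colon. Stomach arrays were scanned at 10 µm and the others at 5 µm.

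Duodenum and jejunum samples shared arrays as pairs of opposite dye: duodenum 1 with jejunum 3, duodenum 2 with jejunum 1, and duodenum 3 with jejunum 2. Colon 1 and 2 were the channels of one hybridisation, and colon 3 came from another scan of a slide with the same barcode. Damaged spots shared between those scans numbered 15, of 31 and 38, against at most 2 in 54 pairs of scans of different slides. Scatter between the scans (0.36 on the log2 scale for 1672 bright spots) exceeded that between channels within each (0.22 and 0.13), so a second scan of one hybridisation was not established and the 3 colon samples were kept apart. Stomach and ileum samples had an array each. Scan days also followed the segments: the stomach was scanned on one day of its own, duodenum 2 and jejunum 1 on day 3, the other duodenal and jejunal samples on day 2, the ileum on days 4, 5 and 6, and the colon on days 7 and 8.

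Of 41372 non-control spots, 41012 distinct probes remained. Gene names came from the scanner files, brought up to date through the RefSeq gene table: 10942 probes matched through an accession, 5035 through a current symbol and 3355 through an older one, and 21680 kept the name in the file. Genes named in the text carry a symbol that is not a provisional identifier (15208 genes). Some genes that the rule names are not reported here. No genome came with the series, so no positions are given.

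Processed signals were put on the log2 scale and the 75th percentile of each sample was subtracted. Spots flagged by the scanner software as non-uniform or population outliers were left out. A probe was tested when it was well above background in every sample of at least 1 segment (38846 probes), and the brightest probe stood for each gene (33833 genes). Models were fitted with limma 3.58.1 in R 4.3.3, with segment and dye as fixed terms and the slide as a random block (correlation 0.361, 9 residual degrees of freedom), and moderated with an intensity trend. Benjamini-Hochberg adjustment ran over all genes of a contrast, the tests were two-sided, and an adjusted p under 0.05 was called. Limma called 0 genes for the dye term (644 at an unadjusted p under 0.05), and the median absolute dye effect was 0.129 on the log2 scale.

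There were 4 contrasts: stomach minus the mean of duodenum, jejunum and ileum (the small bowel, 9 samples); duodenum minus jejunum; ileum minus jejunum; and colon minus the small bowel. An F test covered all 5 segments. A gene counted as highest in a segment when it exceeded each of the other 4 with adjusted p under 0.05. Values are given as folds, and as log2 differences with the standard error (SE) of the fit. Where a gene was not well above background on any sample of its lower side, the fold is a bound ("at least"), taken at the lowest signal that counted as well above background in each sample. Where it was saturated in every sample of its higher side, the bound is the difference of the segment means. Folds of genes saturated in only some samples of a side are fitted values on signals at the limit of the scanner. These were Clps, Pdia2, Atp4a, Dcn, Muc5ac, Chia and Ghrl (stomach 3), S100g (duodenum 1 and 3), Fabp1 (jejunum 1, 2 and 3 and ileum 2), Fabp2 (jejunum 1 and ileum 2), Guca2a (jejunum 3 and ileum 3), Apoa4 (jejunum 1), Tff3 (jejunum 2 and ileum 2 and 3), Defa24 (ileum 2 and 3) and Zg16 (ileum 3).

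Gene lists were written before the data were examined, as were the contrasts, the terms of the model, the naming rule and most alternatives. After a first fit had been seen, a filter on missing values was removed, the contrasts were solved exactly in place of an approximation, and the block correlation was estimated over all genes. The 38 lists were parietal cell and acid secretion, chief cell, gastric surface and neck mucous cell, gastric endocrine cell, intestinal endocrine cell, brush border digestive enzymes, sugar transport and handling, amino acid and peptide transport, lipid absorption and lipoprotein assembly, cholesterol synthesis, ileal bile acid and cobalamin uptake, duodenal iron, calcium and folate uptake, bicarbonate, chloride and proton transport, aldosterone-responsive sodium and potassium transport, aquaporins, claudins and tight junctions, goblet cell, Paneth cell and antimicrobial, crypt stem and progenitor, cell proliferation, regional transcription factors, Hox genes, xenobiotic metabolism and efflux, mitochondrial oxidative phosphorylation, ketogenesis and fatty acid oxidation, and MHC class II presentation. Markers of other cells the suspensions could hold made up the rest: T cells and intraepithelial lymphocytes, B cells and plasma cells, macrophages and dendritic cells, mast cells, smooth muscle, fibroblasts and matrix, endothelium, enteric neurons and glia, red blood cells, pancreatic acinar cells, squamous forestomach epithelium, and dissociation stress and immediate early genes. Each list was tested in each contrast with camera, preset inter-gene correlation 0.01, adjusted over all 152 tests, and again with the correlation estimated from the data. Of 78 list shifts called, 30 were also called with the estimated correlation. Members were also adjusted over the list alone.

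Named genes followed a rule: the 8 largest changes in each direction of a contrast among genes that passed, whose samples did not overlap and which were well above background throughout the higher side; up to 4 members of each list, largest first, and up to 2 in the opposite direction; the 8 genes most distinctly highest in each segment; a set of known segment markers; and the Hox genes. Of those markers, Cdx1, Mki67, Lgr5 and Olfm4 did not pass the filter and were not tested.

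The number of arrays limits the precision. On simulated data with the spread of these samples, the fit recovered 15% of 2-fold and 78% of 4-fold changes for the stomach contrast, 17% and 67% for duodenum against jejunum, 15% and 67% for ileum against jejunum, and 11% and 62% for the colon, each from 100 changed genes among 33833. Alternatives covered the dye term, the blocks, background correction, scaling, the filter, flagged spots, probe summary, threshold, variance trend, the deposited value table, subsets of the segments, the correlation used in camera and each sample left out. A further 4, named below, were chosen after seeing the data. The other channel of the stomach, ileum and colon 3 arrays was not compared. Values were read and plotted with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.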

Results

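Transcript levels were measured on whole-genome arrays in mucosal cell suspensions from the stomach, duodenum, jejunum, ileum and colon of rats, with 3 samples per segment. Median processed intensities were 782, 847 and 857 in stomach 1 to 3, 323, 266 and 409 in duodenum 1 to 3, 259, 411 and 323 in jejunum 1 to 3, and 300.1, 758.5 and 1048 in ileum 1 to 3. In colon 1 to 3 they were 184.2, 183.5 and 92.4. The percentage of probes well above background was 95.4, 96.7 and 97.1 in the stomach, where the scanner software set a lower limit, and 81.3, 64.7 and 92.5 in the duodenum, 52.4, 87.9 and 89.6 in the jejunum, 44.4, 85.0 and 83.9 in the ileum and 74.5, 90.6 and 78.8 in the colon. Across genes, which are not independent replicates, samples of one segment correlated at 0.916 (jejunum) to 0.988 (stomach). Duodenal and jejunal samples on one array correlated at 0.936 to 0.987, and those on different arrays at 0.912 to 0.965. Errors are SE of the limma fit unless SD is stated. For every gene named, the samples of both sides did not overlap unless said otherwise. In a comparison of 3 samples with 3, 10% of unchanged genes would do so by chance.

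The first question was which transcripts differ along the tract and which are highest in one segment. Limma's F test called 14216 of 33833 genes, and 2564 genes were higher in one segment than in each of the other 4. Of these, 1333 were highest in the stomach, 20 in the duodenum, 14 in the jejunum, 61 in the ileum and 1136 in the colon. Stomach genes included Clps, Pdia2, Atp4a and Dcn, and the smallest of the 4 folds was 341 for Pdia2, 253 for Atp4a and 116 for Dcn. In the duodenum, the iron exporter Slc40a1 exceeded each other segment by at least 3.85-fold, Ugt2b7 by 3.65-fold and the homeobox factor Pdx1 by 3.26-fold. Jejunal genes included Dnase1 (4.98-fold), the incretin Gip (4.08-fold) and the fatty acid binding protein Fabp2 (3.56-fold). Ileal genes included the bile acid binding protein Fabp6, saturated in all 3 ileal samples. The MHC class II chain RT1-Ba exceeded each other segment by 37.9-fold and the phospholipase Plb1 by 30.4-fold. Colon genes were led by Mptx1, Thbs4 and Ccn3, with smallest folds of 360.0, 137 and 78.3. Counts rested in part on single samples. Without stomach 3, the total was 1703 and the stomach count 753, and without colon 1 the colon count was 713. The ileal count was 31 without duodenum 1 and 29 without ileum 3. The duodenal count was 13 without stomach 1, 12 without stomach 2, 2 without duodenum 1, 8 without duodenum 2, 2 without jejunum 3, 13 without ileum 3 and 12 without colon 1 or colon 2. The jejunal count was 9 without stomach 3, 2 without duodenum 1, 7 without duodenum 2, 27 without duodenum 3, 4 without jejunum 1, 147 without jejunum 2, 1 without jejunum 3, 8 without ileum 1, 23 without ileum 2, 7 without colon 1 and 22 without colon 3.

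**Figure D1:**
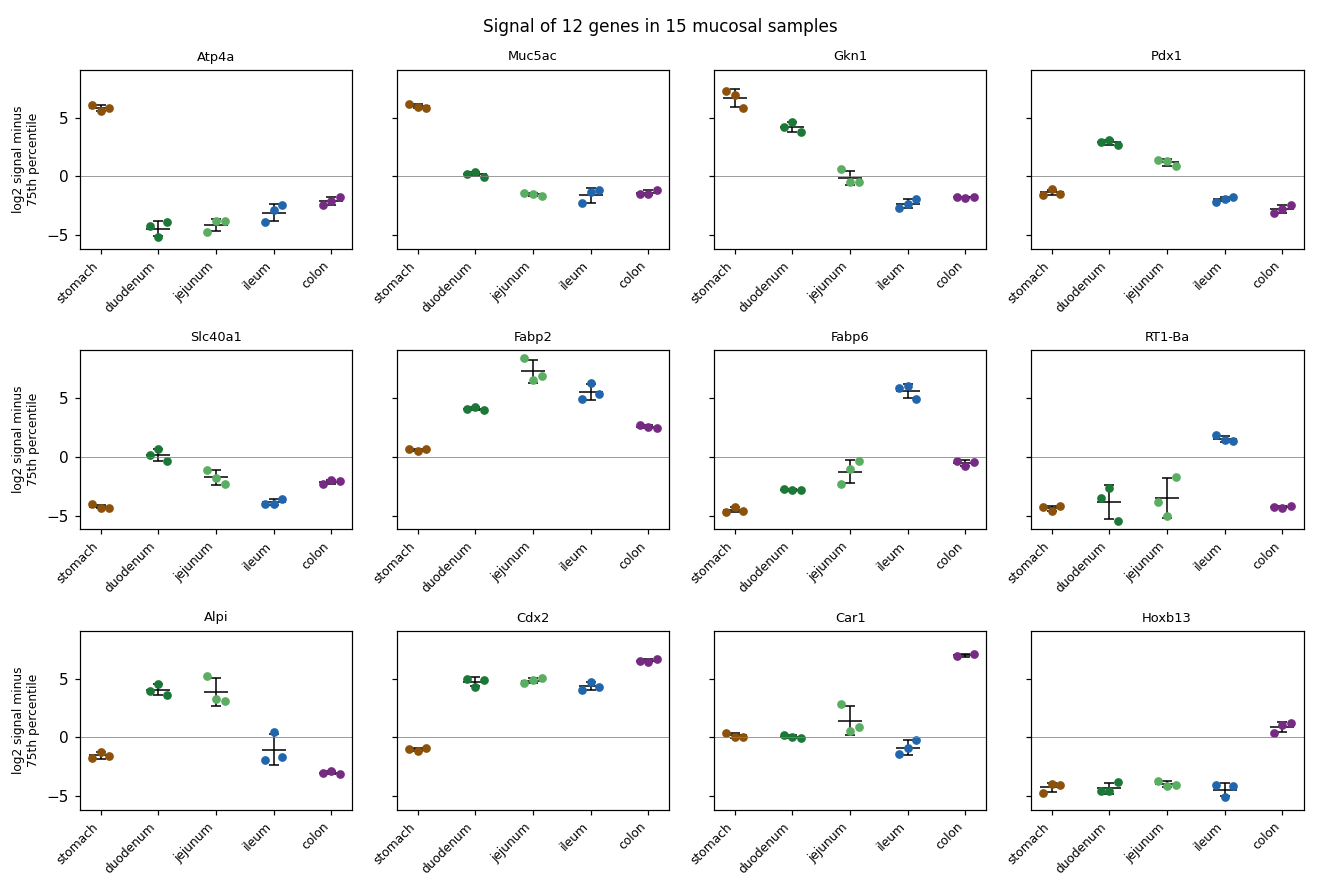
Log2 processed signal minus the 75th percentile of the sample (y axis) for 12 genes in 5 segments; points are samples, horizontal bars means and error bars SD over 3 samples, except Car1 in the colon, where 1 flagged spot was left out and 2 points remain. Atp4a stood at 5.81 ± 0.24 (SD) in the stomach against -4.44 ± 0.63 in the duodenum, Fabp6 at 5.62 ± 0.58 in the ileum (saturated spots) against -1.25 ± 0.99 in the jejunum, and Car1 at 6.98 ± 0.14 in the colon against -0.87 ± 0.60 in the ileum.

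The stomach was set against the small bowel to ask which transcripts separate the acid-secreting from the absorptive mucosa. Atp4a, the catalytic subunit of the gastric proton pump, was 824-fold higher in the stomach (log2 difference 9.69 ± 0.33, adjusted p = 1.93e-12) and was well above background in 5 of the 9 small bowel samples. Muc5ac, the surface mucin, was 124-fold higher (6.95 ± 0.24, adjusted p = 2.09e-12, 8 of 9 small bowel samples). In the opposite direction, Mttp, which loads lipid onto apolipoprotein B, was at least 892-fold lower (adjusted p = 3.38e-11) and in no stomach sample well above background. The disaccharidase Si was 426-fold lower (-8.73 ± 0.50, adjusted p = 8.55e-10, 2 of 3 stomach samples) and the trefoil peptide Tff3 was 435-fold lower (-8.77 ± 0.28, adjusted p = 1.2e-12). The other largest increases were in Clps, the colipase (1410-fold, 3 of 9 small bowel samples), Pdia2 (452-fold, 8 of 9), Anxa10 (204-fold, 7 of 9), the matrix proteoglycan Dcn (152-fold, 8 of 9), the glutathione transferase Gsta1 (138-fold, 8 of 9) and Pla1a (130.4-fold, 4 of 9). The other largest decreases were in Dmbt1 (508-fold), Gsta2 (473-fold), the fructose transporter Slc2a5 (at least 199.9-fold, in no stomach sample well above background), the diamine oxidase Aoc1 (401-fold, 2 of 3 stomach samples) and the cadherin Cdh17 (359-fold).

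Markers of gastric epithelial cells were higher as groups. Members of a list that are not counted as higher or lower did not pass. Of 10 gastric surface and neck mucous cell genes, 9 were higher, with the same count adjusted over the list alone (median log2 difference 5.03, adjusted p = 7.84e-12). After Muc5ac came Tff1 (at least 88.3-fold), Gkn2 (at least 81.7-fold) and Gkn1 (at least 66.4-fold), all saturated in the stomach and well above background in 8 of 9 small bowel samples. Of 9 chief cell genes, 7 were higher, also over the list alone (median 4.93, adjusted p = 6.34e-08), led by the pepsinogen Pga5 (81.9-fold, 8 of 9 small bowel samples), Cym (44.3-fold) and Chia (32.2-fold). Of 17 parietal cell and acid secretion genes, 10 were higher and 1 was lower (11 higher and 1 lower adjusted over the list alone, median 1.57, adjusted p = 9.76e-06). Beside Atp4a, these included the other pump subunit Atp4b (at least 84.5-fold) and the intrinsic factor Cblif (47.2-fold, 2 of 9 small bowel samples), and the lower one was the mitochondrial creatine kinase Ckmt1 (2.91-fold). Gastric endocrine cell genes were higher in 5 of 8, with the same count over the list alone (median 2.43, adjusted p = 0.00134), led by ghrelin (Ghrl, 19.5-fold, 8 of 9 small bowel samples) and the histidine decarboxylase Hdc (12.2-fold). All 4 of these lists were also called with an estimated correlation.

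Digestive and absorptive groups were lower in the stomach. Lipid absorption and lipoprotein assembly genes were lower in 17 of 22, 1 was higher (Clps) and 4 did not pass (the same over the list alone, median -3.65, adjusted p = 2.74e-15), with Npc1l1, the cholesterol uptake protein, 281-fold lower. Fabp1 was a fitted 232-fold lower (saturated in all jejunal samples and ileum 2). Brush border digestive enzymes were lower in 15 of 19 (16 adjusted over the list alone, median -1.81, adjusted p = 1.48e-12), Mep1b by 149-fold. Sugar transport and handling genes were lower in 9 of 12, also over the list alone (median -1.83, adjusted p = 8.58e-09). The fructokinase Khk was 17.5-fold lower. Of 12 goblet cell genes, 7 were lower and 2 higher, also over the list alone (median -1.03, adjusted p = 1.21e-05). Zg16 was 121-fold lower. Of 14 genes for Paneth cells and antimicrobial products, 8 were lower and 1 higher (8 and 2 over the list alone, median -3.42, adjusted p = 2.29e-06), with Dmbt1 lowest. The defensin Defa24 was 211-fold lower, and 327-fold without jejunum 1. Intestinal endocrine cell genes were lower in 8 and higher in 3 of 15, also over the list alone (median -0.84, adjusted p = 2.65e-05), with Tac1 43.0-fold (2 of 3 stomach samples) and secretin (Sct) 39.0-fold lower. Ileal bile acid and cobalamin uptake genes were lower in 7 and higher in 1 of 13 (8 and 1 over the list alone, median -1.21, adjusted p = 5.49e-05), Slc51b by 44.9-fold. Claudins and tight junction genes were lower in 10 and higher in 1 of 21, also over the list alone (median -0.77, adjusted p = 1.21e-05). Cldn18 was the higher one (40.1-fold, 8 of 9 small bowel samples) and Cldn7 was 29.0-fold lower. These 8 lists were also called with an estimated correlation.

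Further lists lost their call with an estimated correlation, whose adjusted p comes second. Duodenal iron, calcium and folate uptake genes were lower in 11 and higher in 2 of 19 (13 and 2 over the list alone, median -0.99, adjusted p = 8.42e-07 and 0.0739). The calcium binding protein S100g was 80.0-fold and the ferroxidase Heph 42.8-fold lower. Xenobiotic metabolism and efflux genes were lower in 20 and higher in 5 of 40 (23 and 5 over the list alone, median -0.80, adjusted p = 3.8e-07 and 0.0571). Amino acid and peptide transport genes were lower in 8 and higher in 5 of 19, also over the list alone (median -0.12, mean -1.07, adjusted p = 0.01 and 0.0864). The peptide transporter Slc15a1 was 334-fold lower (2 of 3 stomach samples), and the median was -0.28 without stomach 3, -0.19 without duodenum 2 and -0.26 without ileum 1. Ketogenesis and fatty acid oxidation genes were lower in 13 and higher in 1 of 26 (16 and 2 over the list alone, median -0.69, adjusted p = 6.24e-06 and 0.134), Acaa2 by 3.63-fold. Cholesterol synthesis genes were lower in 9 and higher in 2 of 20 (11 and 5 over the list alone, median -0.65, adjusted p = 0.000469 and 0.207). Mitochondrial oxidative phosphorylation genes were lower in 13 and higher in 9 of 40 (15 and 13 over the list alone, median -0.21, adjusted p = 0.0127 and 0.603). Neither normexp (adjusted p = 0.355) nor quantile normalisation (0.74) kept the call. Atp5f1a was 8.81-fold lower. The median was -0.35 without stomach 1, -0.14 without stomach 2 (adjusted p = 0.0628), -0.09 without stomach 3 and -0.11 without ileum 2. Regional transcription factors were lower in 10 and higher in 5 of 24 (10 and 6 over the list alone), with a median of 0.12, a mean of -0.59 and a test in the lower direction (adjusted p = 0.0306 and 0.141). The intestinal factor Cdx2 was 50.6-fold lower and the foregut factor Sox2 10.7-fold higher (1 of 9 small bowel samples). That median was 0.07 without duodenum 2 or ileum 3. The list was not called without duodenum 3 (adjusted p = 0.0542) or jejunum 1 (0.0814), with normexp (0.127) or with quantile normalisation (0.164). Hox genes were higher in 6 of 24, also over the list alone (median 0.53, adjusted p = 0.0292 and 0.449), led by Hoxa4 (4.85-fold, 2 of 9 small bowel samples). The list was not called without stomach 2 (adjusted p = 0.0631), with normexp (0.317), with quantile normalisation (0.101) or without the filter on dim probes (0.0502).

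Markers of other cell types and of tissue handling differed as well. Fibroblast and matrix genes were higher in the stomach in 10 of 16, also over the list alone (median 2.52, adjusted p = 3.74e-06, adjusted p = 0.0611 with an estimated correlation), with Dcn first and Col6a1 16.2-fold higher (5 of 9 small bowel samples). Endothelial genes were higher in 9 of 12, also over the list alone (median 1.67, adjusted p = 0.000537, adjusted p = 0.0864 with an estimated correlation), Tek by 5-fold (8 of 9 small bowel samples). Enteric neuron and glia genes were higher in 5 of 13, also over the list alone (median 0.67, adjusted p = 0.0305, adjusted p = 0.41 with an estimated correlation), among them Elavl4 by 3.64-fold (7 of 9 small bowel samples). Dissociation stress and immediate early genes were lower in 15 and higher in 2 of 20 (15 and 3 over the list alone, median -2.13, adjusted p = 1.52e-11, also called with an estimated correlation), with Fos 41.1-fold, Hspa1a 29.8-fold and Dusp1 21.2-fold lower. The list's mean level was -1.76 to -1.83 in the stomach samples and -0.27 to 0.76 in the small bowel samples. MHC class II genes were lower in 7 of 8, also over the list alone (median -1.50, adjusted p = 3.17e-06, also called with an estimated correlation). Ctss was 7.26-fold lower. T cell and intraepithelial lymphocyte genes were lower in 7 of 17, also over the list alone (median -0.68, adjusted p = 0.000106, adjusted p = 0.103 with an estimated correlation), Gzma by 36.9-fold and Cd3g by 13.1-fold. Cell proliferation genes were lower in 14 of 28 (16 over the list alone, median -0.88, adjusted p = 3.29e-09, adjusted p = 0.207 with an estimated correlation), Aurkb by 9.21-fold (8 of 9 small bowel samples) and Ccnb1 by 8.41-fold. Smooth muscle genes were not called (4 higher and 1 lower of 10, the same over the list alone, adjusted p = 0.0501), but were called as higher without stomach 1 (adjusted p = 0.0428), duodenum 1 (adjusted p = 0.0364), duodenum 2 (adjusted p = 0.0382) or ileum 3 (adjusted p = 0.0467). They were also called without the dye term, array block, filter on dim probes, intensity trend, colon samples, or duodenum 2 and jejunum 1, and with normexp, non-uniform and outlier spots kept, or scan day as block (adjusted p = 0.0373 to 0.0498). Other lists that were not called included crypt stem and progenitor (1 higher and 2 lower of 14, the same over the list alone, adjusted p = 0.162), red blood cells (1 higher of 4, also over the list alone, adjusted p = 0.415) and squamous forestomach epithelium (2 higher of 10, also over the list alone, adjusted p = 0.555). Pancreatic acinar cell genes, Clps among them, were higher in 6 of 19 (7 over the list alone, median 0.13), and the list was not called (adjusted p = 0.224), except with normexp (adjusted p = 0.0255).

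**Figure D2:**
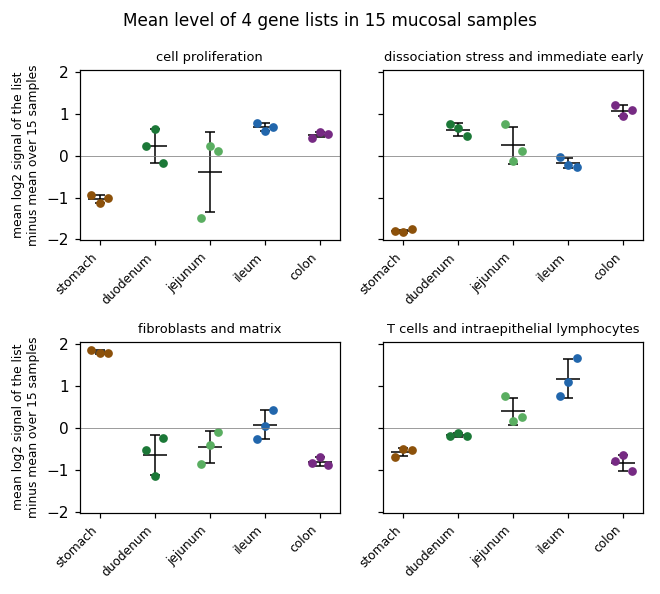
Mean log2 signal of the members of 4 gene lists, minus the mean over 15 samples (y axis), in 5 segments; points are samples, horizontal bars means and error bars SD over 3 samples. Stomach samples were lowest for dissociation stress and immediate early genes (-1.83 to -1.76) and highest for fibroblasts and matrix (1.79 to 1.87), and jejunum 1 had the lowest level of cell proliferation genes (-1.49).

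In all, 5292 genes were higher and 3970 lower in the stomach than in the small bowel. The median difference over all genes was 0.29 with scaling to the 75th percentile, 0.11 with quantile normalisation and -0.06 with normexp background correction. The higher and lower counts were 4317 and 4543 with normexp, 6313 and 3588 with median scaling over bright probes, and 4394 and 4079 with the filter without the stomach flags. They were 2374 and 3714 among genes well above background in all samples, a filter that depends on the change itself. Among the 11278 dimmest genes by the mean of both sides 1569 were higher and 291 lower, and among the 11278 brightest 1939 were higher and 2499 lower. Leaving out single samples changed the higher count to 3274 without stomach 1, 3392 without stomach 2 and 2942 without stomach 3. All stomach arrays were scanned on one day of their own, so segment and scan batch cannot be told apart here. With scan day as a random block, 2533 genes were higher and 2486 lower.

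Duodenum and jejunum, whose samples shared arrays in pairs, were compared to ask what separates neighbouring segments. The stomach-type mucous genes Gkn1 (21.7-fold, log2 difference 4.44 ± 0.27, adjusted p = 3.8e-07), Tff2 (19.5-fold, 4.29 ± 0.29, adjusted p = 6.6e-07) and Gkn2 (16.7-fold, 4.06 ± 0.32, adjusted p = 1.73e-06) were higher in the duodenum. The glutathione transferase Gsta1 was 9.01-fold higher (3.17 ± 0.22, adjusted p = 8.81e-07) and the alcohol dehydrogenase Adh7 10.09-fold higher (3.34 ± 0.34, adjusted p = 4.41e-05, 2 of 3 jejunal samples). Lower in the duodenum were the endonuclease Dnase1 (26.7-fold, -4.74 ± 0.47, adjusted p = 3.54e-05), neurotensin (Nts, 9.04-fold, -3.18 ± 0.24, adjusted p = 1.24e-06) and Fabp2 (8.54-fold, -3.09 ± 0.32, adjusted p = 6.24e-05). These 8 genes kept their call whichever sample was left out. Cmahp was 7.42-fold lower, and 4.11-fold without jejunum 3. The next 5 genes lost their call, but kept their direction, without single samples. The pancreatic amylase Amy2a3 was 19.1-fold higher (1 of 3 jejunal samples), 33.0-fold without jejunum 2, and 10.6-fold and not called without jejunum 3 (adjusted p = 0.109). Tff1 was 7.51-fold higher. It was not called without duodenum 1 (9.33-fold, adjusted p = 0.151) or jejunum 3 (7.54-fold, adjusted p = 0.24). The procarboxypeptidase Cpb1 was 6.93-fold higher (2 of 3 jejunal samples) and 10.5-fold without jejunum 2. It was not called without duodenum 1 (6.22-fold, adjusted p = 0.201) or jejunum 3 (4.25-fold, adjusted p = 0.294). The protease inhibitor Csta was 7.54-fold lower, 4.43-fold without jejunum 1 and 12-fold without jejunum 2. It was not called without duodenum 1 (7.55-fold, adjusted p = 0.201) or jejunum 3 (8.70-fold, adjusted p = 0.131). Stfa3 was 6.54-fold lower and not called without duodenum 1 (5.57-fold, adjusted p = 0.466) or jejunum 3 (8.56-fold, adjusted p = 0.17).

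Mucous, iron-handling and pancreatic groups were higher in the duodenum. Of 10 gastric surface and neck mucous cell genes, 5 were higher (5 higher and 1 lower over the list alone, median 1.07, adjusted p = 1.25e-11, also called with an estimated correlation). Duodenal iron, calcium and folate uptake genes were higher in 5 of 19 (6 over the list alone, median 0.29, adjusted p = 4.62e-07, adjusted p = 0.0659 with an estimated correlation), and the median was 0.18 without jejunum 3. Among them, the ferric reductase Cybrd1 was 6.19-fold higher, 9.84-fold without jejunum 1, and not called without duodenum 1 (5.63-fold, adjusted p = 0.229) or jejunum 3 (4.33-fold, adjusted p = 0.314). S100g was 3.76-fold higher and not called without jejunum 3 (3.18-fold, adjusted p = 0.131). Pancreatic acinar cell genes were higher in 2 of 19 (5 over the list alone, median 0.48, adjusted p = 1.26e-05, also called with an estimated correlation), Amy2a3 and Cpb1, with a median of 0.74 without duodenum 1 and 0.30 without jejunum 1. The list was not called among genes well above background in all samples (median -0.01, adjusted p = 0.613), a filter that drops Amy2a3 and Cpb1. Dissociation stress and immediate early genes had a median of 0.38 (adjusted p = 7.57e-06, adjusted p = 0.0606 with an estimated correlation), while limma called 0 of 20 members, 6 higher at an unadjusted p under 0.05 and 3 over the list alone. The median was 0.25 without duodenum 1, and the list was not called without jejunum 2 (adjusted p = 0.0651). Cell proliferation genes had a median of 0.63 (adjusted p = 1.26e-06, adjusted p = 0.318 with an estimated correlation), while limma called 0 of 28, 5 at an unadjusted p under 0.05 and 0 over the list alone. That median was 0.14 without duodenum 2 (adjusted p = 0.239), 0.98 without duodenum 3, -0.02 without jejunum 1 (adjusted p = 0.902) and 1.104 without jejunum 2. Without both duodenum 2 and jejunum 1 the list was called as lower (median -0.11, adjusted p = 0.00185). The list's level was -1.49 in jejunum 1 and 0.64 in duodenum 2, which shared an array, and -0.18 to 0.23 in the other 4 samples.

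Several absorptive and secretory groups were lower in the duodenum, with exceptions. Genes for Paneth cells and antimicrobial products were higher in 3 of 14 (4 higher and 1 lower over the list alone). As a list they were not called (median -0.33, test in the higher direction, adjusted p = 0.257), except without jejunum 3 (median 0.41, adjusted p = 0.00824) or with normexp (median -0.01, adjusted p = 0.0378). Sugar transport and handling genes were not called (median -0.16, adjusted p = 0.0677), but were without jejunum 2 (median -0.29, adjusted p = 0.0102), jejunum 3 (median -0.35, adjusted p = 0.00632) or ileum 2 (adjusted p = 0.0347). They were also called without the dye term and with the replicate block, normexp or the mean of all probes (adjusted p = 0.00787 to 0.0356). Lipid absorption and lipoprotein assembly genes were lower in 3 of 22 (14 over the list alone, median -1.04, adjusted p = 1.68e-14, also called with an estimated correlation), Fabp2 first, and the median was -0.50 without jejunum 1. Brush border digestive enzymes were lower in 2 and higher in 1 of 19 (10 and 1 over the list alone, median -0.78, adjusted p = 8.58e-09, adjusted p = 0.112 with an estimated correlation), with a median of -0.36 without jejunum 1 and -1.26 without jejunum 2. Goblet cell genes were lower in 4 of 12 (5 over the list alone, median -0.57, adjusted p = 4.42e-10, also called with an estimated correlation), with a median of -0.92 without duodenum 1. Guca2a, the precursor of guanylin, was 4.46-fold lower and not called without duodenum 1 (3.72-fold, adjusted p = 0.272) or jejunum 3 (5.23-fold, adjusted p = 0.077). Intestinal endocrine cell genes were lower in 5 of 15 (6 over the list alone, median -0.29, adjusted p = 3.73e-06, also called with an estimated correlation), Nts first, with a median of -0.12 without duodenum 2. Ketogenesis and fatty acid oxidation genes were lower in 3 of 26, also over the list alone (median -0.16, adjusted p = 0.000148, adjusted p = 0.208 with an estimated correlation). The median was -0.04 without duodenum 3 (adjusted p = 0.158), -0.03 without jejunum 1, -0.30 without jejunum 2 and -0.25 without jejunum 3. Amino acid and peptide transport genes had a median of -0.30 (adjusted p = 0.00434, adjusted p = 0.0571 with an estimated correlation) with 0 of 19 called by limma, 2 higher and 5 lower at an unadjusted p under 0.05 and 1 higher over the list alone. The median was -0.49 without duodenum 3 and -0.22 without jejunum 1 (adjusted p = 0.0566). Aquaporins were lower in 1 of 10, also over the list alone (median -0.25, adjusted p = 0.0225, adjusted p = 0.14 with an estimated correlation). The list was not called without duodenum 3 (adjusted p = 0.0657), jejunum 1 (adjusted p = 0.0584) or jejunum 2 (adjusted p = 0.0682), and its median was -0.51 without duodenum 1 and -0.44 without jejunum 3. Ileal bile acid and cobalamin uptake genes were lower in 1 of 13 (3 lower and 1 higher over the list alone, median -0.23, adjusted p = 0.0458, adjusted p = 0.181 with an estimated correlation), and gastric endocrine cell genes had a median of -0.28 (adjusted p = 0.029, adjusted p = 0.131 with an estimated correlation) with 0 of 8 called by limma, 2 lower at an unadjusted p under 0.05 and 0 over the list alone. Of these last lists, the first was not called without duodenum 1 (adjusted p = 0.0986), duodenum 2 (median 0.01, adjusted p = 0.111), duodenum 3 (median -0.56, adjusted p = 0.062), jejunum 1 (adjusted p = 0.25), jejunum 3 (adjusted p = 0.0567), ileum 1 (adjusted p = 0.0505) or colon 3 (adjusted p = 0.0517) and had a median of -0.39 without jejunum 2. The second was not called without duodenum 1 (adjusted p = 0.086), duodenum 3 (adjusted p = 0.0598) or jejunum 1 (median -0.10, adjusted p = 0.548) and had a median of -0.47 without jejunum 2 and -0.52 without jejunum 3. With only duodenum and jejunum fitted, 4 lists of this paragraph were not called: amino acid and peptide transport (adjusted p = 0.0501), aquaporins (0.174), ileal bile acid and cobalamin uptake (0.0523) and gastric endocrine cells (0.174).

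Several immune lists were lower in the duodenum. On the array of duodenum 3 and jejunum 2, of these only T cells were (median -0.39). MHC class II, mast cell and macrophage genes stood at 0.03, 0.06 and 0.10 there, and lower on the other arrays. Of the lists for stroma, vessels, muscle and nerve only fibroblast and matrix genes were called. B cell and plasma cell genes were not called (median -0.06, adjusted p = 0.638), except without jejunum 1 (median -0.27, adjusted p = 0.0473). T cell and intraepithelial lymphocyte genes had a median of -0.47 (adjusted p = 3.73e-06, also called with an estimated correlation), with 0 of 17 called by limma, 6 lower at an unadjusted p under 0.05 and 2 over the list alone. Mast cell genes had a median of -0.54 (adjusted p = 0.000351, also called with an estimated correlation, adjusted p = 0.0567 without jejunum 3), with 0 of 10 called, 4 lower unadjusted and 2 over the list alone. MHC class II genes had a median of -0.65 (adjusted p = 0.000253, adjusted p = 0.112 with an estimated correlation, median -0.16 and adjusted p = 0.217 without jejunum 3), with 0 of 8 called, 4 lower unadjusted and 0 over the list alone. Macrophage and dendritic cell genes were lower in 1 of 12 (4 over the list alone, median -0.38, adjusted p = 0.000234, also called with an estimated correlation), with a median of -0.11 without duodenum 2, -0.60 without duodenum 3, -0.19 without jejunum 1 and -0.62 without jejunum 2. Fibroblast and matrix genes had a median of -0.27 (adjusted p = 0.0227, adjusted p = 0.38 with an estimated correlation), with 0 of 16 called, 3 lower unadjusted and 0 over the list alone. The list was not called without duodenum 2 (median -0.06, adjusted p = 0.187), jejunum 2 (adjusted p = 0.0688) or jejunum 3 (median -0.12, adjusted p = 0.421), nor with only duodenum and jejunum fitted (adjusted p = 0.0631). Its median was -0.42 without duodenum 3. In all, 83 genes were higher and 88 lower in the duodenum. Higher and lower counts were 18 and 10 without duodenum 1, 52 and 39 without duodenum 2, 187 and 227 without duodenum 3, 529 and 633 without jejunum 2, 17 and 11 without jejunum 3, and 136 and 213 without colon 3. The lower count was 50 without stomach 3 and 58 without colon 1.

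Ileum was set against jejunum to ask what changes towards the distal small bowel. Fabp6 was at least 117-fold higher in the ileum (adjusted p = 1.07e-07, 2 of 3 jejunal samples), and without jejunum 1 the fitted fold was 81.3 in place of 124. The phospholipase Plb1 was 45.7-fold higher (log2 difference 5.51 ± 0.65, adjusted p = 0.000214, 2 of 3 jejunal samples, 80.8-fold without ileum 3), RT1-Ba 37.9-fold (5.24 ± 0.64, adjusted p = 0.000275, 1 of 3 jejunal samples, 59.1-fold without jejunum 3) and Ly6al 37.4-fold (5.22 ± 0.39, adjusted p = 1.57e-06). Further increases were in Tmigd1 (27.3-fold), the dual oxidase Duox2 (22.8-fold, 2 of 3 jejunal samples), the gut hormone peptide YY (Pyy, 16.1-fold) and the globin Hbb-b1 (16-fold, 2 of 3 jejunal samples). Adh1c was 28.7-fold lower (-4.84 ± 0.28, adjusted p = 1.07e-07). Intestinal alkaline phosphatase, Alpi, was 31.8-fold lower (-4.99 ± 0.55, adjusted p = 9.14e-05, 2 of 3 ileal samples), 20.5-fold without jejunum 1 and 53.8-fold without ileum 2. Ghrl was 34.5-fold lower (2 of 3 ileal samples), 18.1-fold without ileum 1 and 69.9-fold without ileum 2. Leg1 was 85.0-fold lower (1 of 3 ileal samples), 42.2-fold without jejunum 1, 148-fold without jejunum 2 and 45.1-fold without ileum 3, and its log2 difference was -7.64 without ileum 2. Stfa3 was 69.6-fold lower (1 of 3 ileal samples) and 41.2-fold without jejunum 1. Papss2, which makes the sulphate donor PAPS, was 44.7-fold lower, 24.4-fold without jejunum 1, 70.8-fold without jejunum 2 and 76.5-fold without ileum 2. Csta was 38.0-fold lower (2 of 3 ileal samples), 18.9-fold without jejunum 1 and 70.7-fold without jejunum 2. Aldh1a4 was 34.3-fold lower, 21.7-fold without jejunum 1 and 18.3-fold without ileum 3.

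Immune, bile acid and antimicrobial groups were higher in the ileum. MHC class II genes were higher in 5 of 8, also over the list alone (median 2.69, adjusted p = 3.59e-07, also called with an estimated correlation). After RT1-Ba, RT1-Bb was 8.71-fold higher. T cell and intraepithelial lymphocyte genes were higher in 2 of 17 (3 over the list alone, median 0.54, adjusted p = 0.000638, adjusted p = 0.141 with an estimated correlation), Cd3e by 5.54-fold (2 of 3 jejunal and 2 of 3 ileal samples) and Cd8a by 4.23-fold. The median was 0.88 without jejunum 1, 0.44 without jejunum 2 (adjusted p = 0.0508), 0.83 without ileum 1 and 0.32 without ileum 3. Ileal bile acid and cobalamin uptake genes were higher in 3 of 13, also over the list alone (median 0.50, adjusted p = 0.00466, adjusted p = 0.0606 with an estimated correlation, adjusted p = 0.089 without jejunum 2, median 0.33 without ileum 2). After Fabp6, the exporter subunit Slc51b was 6.14-fold higher. Genes for Paneth cells and antimicrobial products were higher in 5 of 14 (7 higher and 2 lower over the list alone, median 1.45, adjusted p = 0.00122, also called with an estimated correlation), led by Duox2, and the median was 0.51 without jejunum 1 and 2.30 without jejunum 3. Fibroblast and matrix genes were higher in 2 and lower in 1 of 16 (6 and 1 over the list alone, median 0.62, adjusted p = 0.0273, adjusted p = 0.391 with an estimated correlation), with a median of 0.38 without jejunum 1 and no call without jejunum 2 (adjusted p = 0.11) or ileum 3 (adjusted p = 0.113). Cell proliferation genes were higher in 1 of 28 (18 over the list alone, median 1.14, adjusted p = 1.38e-08, adjusted p = 0.222 with an estimated correlation), and the median was 0.45 without jejunum 1, whose level of this list lay below the other samples. B cell and plasma cell genes had a median of 0.55 and were not called (adjusted p = 0.126), except with scan day as block (median 0.96, adjusted p = 0.0435). Limma called 0 of 9, 3 higher at an unadjusted p under 0.05 and 0 over the list alone.

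Nutrient handling groups were lower in the ileum. Sugar transport and handling genes were lower in 9 of 12 (10 over the list alone, median -1.60, adjusted p = 2.04e-10, also called with an estimated correlation), among them the glucose-6-phosphatase G6pc1 by 7.05-fold (4.53-fold without jejunum 1). Lipid absorption and lipoprotein assembly genes were lower in 8 of 22 (13 over the list alone, median -1.34, adjusted p = 1.27e-09, adjusted p = 0.103 with an estimated correlation), with a median of -0.80 without jejunum 1. Apoa4 was 17.1-fold lower, 10.7-fold without jejunum 1, 36.6-fold without ileum 2 and 11.3-fold without ileum 3. Brush border digestive enzymes were lower in 6 and higher in 2 of 19 (9 and 2 over the list alone, median -0.90, adjusted p = 3.94e-05, adjusted p = 0.259 with an estimated correlation), Alpi first, with a median of -0.42 without jejunum 1. Among genes well above background in all samples this test turned to the higher direction (median -0.19, adjusted p = 0.944). Xenobiotic metabolism and efflux genes were lower in 11 and higher in 1 of 40 (18 and 1 over the list alone, median -0.80, adjusted p = 2.49e-10, also called with an estimated correlation). Ketogenesis and fatty acid oxidation genes were lower in 7 of 26 (16 over the list alone, median -0.80, adjusted p = 1.53e-09, also called with an estimated correlation), but not called with normexp (median -0.26, adjusted p = 0.19). Mitochondrial oxidative phosphorylation genes were lower in 14 of 40 (22 over the list alone, median -0.72, adjusted p = 5.02e-14, adjusted p = 0.107 with an estimated correlation), Atp5mc3 by 2.94-fold, but higher with normexp background correction (median 0.23, adjusted p = 0.00319). Duodenal iron, calcium and folate uptake genes were lower in 5 of 19 (6 over the list alone, median -0.42, adjusted p = 6.24e-06, but 0.107 with an estimated correlation and 0.176 with normexp). The median was -0.76 without jejunum 2. S100g was 5.06-fold lower and Slc40a1 4.51-fold (2 of 3 ileal samples). Amino acid and peptide transport genes had 2 of 19 higher (2 higher and 4 lower over the list alone) while the median was -0.45 and the test in the lower direction (adjusted p = 0.028, adjusted p = 0.134 with an estimated correlation). The list was not called without jejunum 1 (median -0.23, adjusted p = 0.19), ileum 1 (0.0512) or ileum 3 (0.0708), with normexp (0.56) or with quantile normalisation (0.239).

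Gastric and goblet markers and regional factors were also lower in the ileum. Gastric endocrine cell genes were lower in 5 of 8 (6 over the list alone, median -1.99, adjusted p = 5.21e-08, also called with an estimated correlation), with chromogranin B (Chgb) 6.67-fold lower, and 4.35-fold without jejunum 1. Gastric surface and neck mucous cell genes were lower in 4 of 10, also over the list alone (median -0.43, adjusted p = 5.41e-05, adjusted p = 0.107 with an estimated correlation, median -0.17 without jejunum 1 and -0.73 without jejunum 2). Gkn2 was 10.4-fold lower (2 of 3 ileal samples). Regional transcription factors were lower in 5 and higher in 1 of 24 (7 and 1 over the list alone, median -0.43, adjusted p = 0.000226, also called with an estimated correlation), among them Pdx1 by 8.76-fold (2 of 3 ileal samples) and Gata4 by 3.87-fold. Goblet cell genes were lower in 5 and higher in 1 of 12 (6 and 2 over the list alone, median -0.42, adjusted p = 0.0238, adjusted p = 0.248 with an estimated correlation, median -0.21 and adjusted p = 0.223 without jejunum 1), Tff3 by 3.68-fold, but the test turned to the higher direction with normexp (median 0.38, adjusted p = 0.0278) and with quantile normalisation (median -0.03, adjusted p = 0.36). Dissociation stress and immediate early genes were lower in 2 and higher in 1 of 20 (3 and 1 over the list alone, median -0.44, adjusted p = 0.00503, adjusted p = 0.238 with an estimated correlation, median -0.19 and adjusted p = 0.155 without jejunum 1, median -0.68 without jejunum 2), and the direction was higher with normexp (median 0.10, adjusted p = 0.195). In all, 497 genes were higher and 938 lower in the ileum, and the median over all genes was 0.10, against -0.13 with normexp and 0.00 with quantile normalisation. Without single samples, higher and lower counts were 297 and 616 (stomach 1), 959 and 1409 (duodenum 3), 179 and 302 (jejunum 1), 1745 and 1905 (jejunum 2), 288 and 353 (ileum 1) and 146 and 351 (ileum 3), and the higher count was 306 without stomach 2, 317 without stomach 3 and 291 without ileum 2. Ileum samples were all Cy3 and scanned on days of their own, so segment and scan batch cannot be told apart. With only Cy3 samples 96 genes were higher and 131 lower.

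Colon was set against the small bowel to ask which transcripts separate large from small bowel mucosa. The pentraxin Mptx1 was 819-fold higher in the colon (log2 difference 9.68 ± 0.52, adjusted p = 2.71e-09, 5 of 9 small bowel samples) and the carbonic anhydrase Car1 113-fold (6.82 ± 0.51, adjusted p = 2.18e-07, 8 of 9). Other large increases were in Thbs4 (195.0-fold, 7 of 9), Ccn3 (134-fold), Cd177 (117-fold, 7 of 9), Rgcc (99.5-fold, 7 of 9) and Sfrp2 (83.9-fold, 6 of 9). Si was at least 349.6-fold lower (adjusted p = 3.26e-08) and the histamine methyltransferase Hnmt at least 222-fold lower (adjusted p = 1.64e-11), neither well above background in any colon sample. Mttp was 550.4-fold lower (-9.10 ± 0.56, adjusted p = 1.33e-08, 1 of 3 colon samples), and the incretin Gip 91.5-fold lower (-6.52 ± 0.50, adjusted p = 1.79e-07). Further decreases were in Pla2g12a (at least 179.9-fold), the amino acid transporter subunit Slc3a1 (at least 66.7-fold), Slc2a5 (at least 89.0-fold) and the xanthine dehydrogenase Xdh (97.5-fold), the first 3 in no colon sample well above background.

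Salt and acid-base transport and Hox genes were higher in the colon. A second adjusted p is for an estimated correlation. Aldosterone-responsive sodium and potassium transport genes were higher in 10 and lower in 1 of 19 (11 and 1 over the list alone, median 1.48, adjusted p = 4.24e-07, also called with an estimated correlation), led by Hsd11b2, which protects the mineralocorticoid receptor from corticosterone (35.6-fold), and Fxyd4 (34.9-fold, 6 of 9 small bowel samples). The channel subunit Scnn1g was 3.64-fold lower. Bicarbonate, chloride and proton transport genes were higher in 11 of 22 (13 higher and 1 lower over the list alone, median 0.84, adjusted p = 0.00467 and 0.133). They were not called with normexp (adjusted p = 0.237). After Car1, Car2 was 38.5-fold higher. Hox genes were higher in 11 and lower in 2 of 24, also over the list alone (median 1.01, adjusted p = 0.000256 and 0.207). Hoxa4 was 47.5-fold (2 of 9 small bowel samples), Hoxb13 32.7-fold (3 of 9) and Hoxa9 14.8-fold (6 of 9) higher. Hoxb1 was 3.09-fold lower. Ketogenesis and fatty acid oxidation genes were higher in 6 and lower in 3 of 26 (8 and 3 over the list alone, median 0.46, adjusted p = 0.00753 and 0.391). They were not called with normexp (adjusted p = 0.437) or quantile normalisation (0.654, median -0.01). Acads was 5.26-fold higher. Mitochondrial oxidative phosphorylation genes were higher in 10 of 40, also over the list alone (median 0.46, adjusted p = 0.000351 and 0.45), Ndufa1 by 4.20-fold. The test turned to the lower direction with normexp (median 0.06, adjusted p = 0.529) and with quantile normalisation (median -0.11, adjusted p = 0.707). Dissociation stress and immediate early genes were higher in 13 and lower in 1 of 20, also over the list alone (median 1.31, adjusted p = 0.000286 and 0.134). Ier3 was 4.93-fold and Egr1 4.75-fold higher. The list's mean level was 0.95 to 1.20 in the colon samples and -0.27 to 0.76 in the small bowel samples.

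Several absorptive and immune groups were lower in the colon. Lipid absorption and lipoprotein assembly genes were lower in 13 and higher in 1 of 22, also over the list alone (median -1.80, adjusted p = 5.04e-08, adjusted p = 0.134 with an estimated correlation). After Mttp, Apoa4 was 71.3-fold lower. Brush border digestive enzymes were lower in 13 and higher in 2 of 19 (14 and 2 over the list alone, median -1.97, adjusted p = 9.38e-06, adjusted p = 0.222 with an estimated correlation), with Enpep 87.2-fold (2 of 3 colon samples) and Alpi 36.9-fold lower (8 of 9 small bowel samples). Sugar transport and handling genes were lower in 7 and higher in 2 of 12 (8 and 2 over the list alone, median -1.40, adjusted p = 0.00177, adjusted p = 0.246 with an estimated correlation). Pck1 was 10.96-fold higher. Genes for Paneth cells and antimicrobial products were lower in 7 and higher in 3 of 14 (8 and 3 over the list alone, median -1.97, adjusted p = 0.0376, adjusted p = 0.165 with an estimated correlation, adjusted p = 0.0626 without duodenum 2 and 0.0634 without colon 2). Reg1a was at least 68.3-fold lower. It was well above background in 0 of 3 colon and 8 of 9 small bowel samples, and without colon 1 its fitted fold was 368 in place of 195.0. MHC class II genes were lower in 6 and higher in 1 of 8, also over the list alone (median -1.98, adjusted p = 0.0037, adjusted p = 0.207 with an estimated correlation), Cd74 by 20.4-fold. T cell and intraepithelial lymphocyte genes were lower in 10 of 17 (11 over the list alone, median -1.39, adjusted p = 0.000282, adjusted p = 0.126 with an estimated correlation), Gzma by 11.6-fold and Cd3g by 6.44-fold. Macrophage and dendritic cell genes were lower in 4 and higher in 1 of 12 (5 and 1 over the list alone, median -0.78, adjusted p = 0.0241, adjusted p = 0.134 with an estimated correlation). The lysozyme Lyz2 was 26.7-fold lower (47.2-fold without colon 1) and Cd14 12.2-fold higher. Not called were amino acid and peptide transport (4 higher and 5 lower of 19, adjusted p = 0.163), B cells and plasma cells (2 lower of 9, adjusted p = 0.299) and mast cells (1 lower of 10, adjusted p = 0.282), each with the same counts over the list alone. The first was called as lower with normexp (adjusted p = 0.00298) and with the mean of all probes (adjusted p = 0.038). Ileal bile acid and cobalamin uptake genes were lower in 4 of 13 (6 lower and 1 higher over the list alone) and not called (adjusted p = 0.057). They were called as lower without ileum 1 (adjusted p = 0.0443) or colon 3 (adjusted p = 0.0473), and with normexp, quantile normalisation or the filter without the stomach flags. In all, 4203 genes were higher and 4448 lower in the colon, and 6054 higher and 3050 lower with normexp, which moved the median over all genes from 0.00 to 0.33. Without colon 1, 2661 genes were higher. All colon arrays came from one slide barcode and scan days of their own, so segment and scan batch cannot be told apart.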

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

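No test of this part was chosen after its result was seen. The arrays of the stomach, of the ileum and of colon 3 also gave a signal in a channel that no comparison here uses, since the labels name no sample of the series for it. The percentage of probes well above background in that other channel was 96.9, 97.4 and 96.0 on the arrays of stomach 1, 2 and 3, 71.0, 86.4 and 91.6 on those of ileum 1, 2 and 3, and 49.8 on that of colon 3. For the samples themselves it is given in Results. The multiplier behind this percentage was lower on the stomach arrays (2.6) than on the ileal arrays (13), so it does not compare the segments. Across 41012 probes, which are not independent replicates, the other channel correlated with the sample of its own array at 0.98 on each stomach array, at 0.73, 0.87 and 0.88 on the arrays of ileum 1, 2 and 3, and at 0.96 on that of colon 3. No group was assigned to these channels, and no biological explanation was tested.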

How the results depend on the processing

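Tests chosen only after seeing the data were the hybridisation as random block, colon 2 and 3 averaged, the filter without the stomach flags, and the fit without duodenum 2 and jejunum 1. Of 141 named changes, 125 kept their direction and their side of the threshold under every alternative that could be computed for them, and 0 reversed. Of the 78 called list shifts, 27 kept both under every alternative and 6 reversed under at least 1. The number of genes that differed between any segments stayed between 9772 and 17664, within 1.5 times of 14216. The counts in the next 2 paragraphs lay beyond 1.5 times of those in the report, and the cause was not tested unless given. No count did so with median scaling over bright probes, the deposited value table, no filter on dim probes, non-uniform and outlier spots kept, the mean of all probes, a change of at least 2-fold, the filter without the stomach flags, or without the colon or the stomach samples. Counting every labelled sample as its own replicate was the same fit and tested nothing.

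Without the dye term, 177 genes were lower in the duodenum than in the jejunum and 26 were highest in the jejunum. Without the array block, which treats samples of a slide as independent, the counts were 31 higher and 14 lower in the duodenum, 6544 higher and 6820 lower in the colon, and 8, 2 and 1734 highest in the duodenum, jejunum and colon. With the replicate number as a block they were 39 higher and 25 lower in the duodenum, 257 higher and 447 lower in the ileum, and 9, 3 and 38 highest in the duodenum, jejunum and ileum. Residual correlation was -0.43 to 0.33 (median -0.11) over the 30 pairs with the same number, and 0.49 to 0.77 for the 3 sharing a slide. Slides joined different numbers, which can lower the former, so pairing by number stays open. Normexp background correction gave 37, 25 and 100 genes highest in the duodenum, jejunum and ileum. Quantile normalisation gave 133 genes lower in the duodenum and 629 highest in the colon. The filter on genes well above background in all samples, which tests 14636 of 33833 genes, gave 2374 higher in the stomach, 28 higher and 43 lower in the duodenum, 2878 lower in the colon, and 544, 8 and 8 highest in the stomach, duodenum and jejunum. At the looser unadjusted p under 0.05, 1479 genes were higher and 1397 lower in the duodenum, and 3770 higher and 3473 lower in the ileum. The same threshold gave 2207, 121, 181, 235 and 2016 genes highest in the stomach, duodenum, jejunum, ileum and colon, 4760 in all. Without the intensity trend there were 55 lower in the duodenum, 306 higher and 411 lower in the ileum, and 13 and 4 highest in the duodenum and jejunum. With scan day as a random block the counts were 2533 higher and 2486 lower in the stomach, 139 lower in the duodenum, 214 higher and 495 lower in the ileum, and 797 and 34 highest in the stomach and ileum.

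Fits on fewer samples gave 151 genes lower in the duodenum (only duodenum and jejunum), 93 higher and 123 lower in the ileum (only ileum and jejunum), and 96 higher and 131 lower there (only their Cy3 samples). With the hybridisation as block, 176 genes were higher and 278 lower in the duodenum, and 35 and 29 were highest in the duodenum and jejunum. With colon 2 and 3 averaged, 167 were lower in the duodenum and 22 highest in the jejunum. Without duodenum 2 and jejunum 1, 46 were lower in the duodenum, 294 higher and 481 lower in the ileum, and 3 and 1887 highest in the jejunum and colon.

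Medians of the 6 list tests that reversed follow. With normexp they were, in the ileum, 0.10 for dissociation stress (-0.44 in the report) and 0.38 for goblet cell genes (-0.42). For oxidative phosphorylation they were 0.23 there and 0.06 in the colon (-0.72 and 0.46). With quantile normalisation the medians were -0.031 for goblet cell genes in the ileum and -0.11 for oxidative phosphorylation in the colon. Brush border enzymes in the ileum (-0.90) were at -0.19 among genes well above background in all samples. Cell proliferation genes in the duodenum (0.63) were at -0.11, and called as lower, without duodenum 2 and jejunum 1, and at -0.019 to 1.104 with each sample left out in turn, lowest without jejunum 1. A list is tested against the other genes, so a median can keep its sign where the test turns. Lists not called for the duodenum also turned, B cells to 0.12 with the replicate block, and Paneth cells to -0.074 and sugar transport to -0.061 without duodenum 2 and jejunum 1. With each sample left out they ranged from -0.274 to 0.167 for B cells, -0.541 to 0.406 for Paneth cells and -0.347 to -0.077 for sugar transport. The causes were not tested. Past the threshold no longer, in the same direction, were 11 lists with normexp, 8 with quantile normalisation, 20 among genes well above background in all samples, 6 with the replicate block, 10 without duodenum 2 and jejunum 1, 5 of 19 with only duodenum and jejunum, 48 with the estimated correlation, and at most 3 with any other alternative on all samples. Of the named changes these were 4 without the array block, 4 with normexp, and at most 2 otherwise on all samples. With only ileum and jejunum they were 6 of 30. The Cy3-only fit gave the same differences, as the dye term absorbs jejunum 3, the only Cy5 sample.

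With each sample left out in turn, counts ranged from 10392 to 15710 for genes that differed between any segments, 2942 (without stomach 3) to 5978 higher and 2886 to 4564 lower in the stomach, 17 to 529 (without jejunum 3 and jejunum 2) and 10 to 633 (duodenum 1 and jejunum 2) in the duodenum, 146 to 1745 (ileum 3 and jejunum 2) and 302 to 1905 (jejunum 1 and jejunum 2) in the ileum, and 2661 (colon 1) to 4667 and 3258 to 4908 in the colon. Genes highest in a segment ranged from 753 to 1435 in the stomach (lowest without stomach 3), 2 to 29 in the duodenum (duodenum 1), 1 to 147 in the jejunum (jejunum 3, highest without jejunum 2), 29 to 63 in the ileum (ileum 3) and 713 to 1440 in the colon (colon 1), 1703 to 2957 in all (stomach 3), and list shifts from 73 to 79. Few probes well above background limit what can be seen in jejunum 1 and ileum 1 (52.4% and 44.4%).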

Other observations

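Peptide YY (Pyy), a hormone of distal endocrine cells, stood at -1.71 ± 0.04 (SD, n = 3 in each segment, log2 signal minus the 75th percentile) in the stomach, -2.38 ± 0.56 in the duodenum, -0.81 ± 0.97 in the jejunum, 3.09 ± 0.26 in the ileum and 4.97 ± 0.19 in the colon. The aquaglyceroporin Aqp3 stood at 0.82 ± 0.08, 0.96 ± 0.08, 1.28 ± 0.51, 1.20 ± 0.52 and 4.53 ± 0.34 in the same order. The ileal bile acid transporter Slc10a2 stood at 1.92 ± 0.54 in the ileum and at 0.41 ± 0.11 to 0.81 ± 0.07 in the other segments, and the factor Klf4 at 6.47 ± 0.24 in the colon and 3.72 ± 0.15 to 4.25 ± 0.22 elsewhere. The first 2 components of the samples held 35.1% and 27.3% of the variance.

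The tests of dim probes, of stomach cells carried into the duodenum, of a single pair of samples and of exchanged channels were chosen only after the result was seen. Other splits of the samples were counted with the real one included. These fits kept non-uniform and outlier spots and took the block correlation from a sample of genes. The real split was refitted in the same way, so its counts differ from those of the report. For genes that differed between any segments, 4 of 100 splits gave as many (14070 in the real split, highest other 16574). The 3 other splits gave 14802 to 16574. A share of 4 in 100 random splits lies under the limit of 0.05 set beforehand, but too near it to exclude chance for this count. Of the 15 pairs of samples placed in a group by each of those 3, 2 to 4 were of 1 segment, 1 or 2 of 1 scan day and 0 or 1 of 1 array, so none followed the scan days or the arrays. For genes highest in 1 segment it was 1 of 100 (2551, highest other 971), for the stomach 1 of 100 (9212, highest other 6531) and for the colon 1 of 100 (8650, highest other 6096), with chance excluded at the same level. Duodenum against jejunum (148, highest other 2268, 2 of 10 splits as large) and ileum against jejunum (1352, highest other 0 by limma, 1 of 10) have too few splits for a share under 0.05. The real duodenal split parts all 3 shared arrays, as only 3 of the 9 others do, and these gave 2268, 0 and 0 genes by limma. At an unadjusted p under 0.05 those 3 gave 7925, 687 and 236, against 2755 in the real split. The unadjusted counts of the real split and the highest other were 7235 and 4347 for the ileum, 12784 and 11988 for the stomach and 12844 and 11020 for the colon.

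With scaling to the 75th percentile, 57.1% of the genes called in the stomach were higher. With normexp, which started from the raw spot signals and so also left out the dye normalisation, 48.7% were higher. That turn cannot be assigned to the background correction alone. The share was 51.9% with the filter without the stomach flags and 50.5% with scan day as a random block. It was 39.0% among genes well above background in all samples, but that filter removes genes by the change itself and decides nothing. With genes ranked by the equally weighted mean of both sides, it was 84.4% among the dimmest and 43.7% among the brightest, and 66.0% and 42.0% without the stomach flags, a difference of 24.0 points, which is consistent with dim probes raised on the stomach arrays. It was 53.0% with quantile normalisation and 63.8% with median scaling over bright probes, so the scaling moved it both ways without turning it. Scan batch and segment cannot be told apart here, and a biological excess of stomach transcripts stays open and untested.

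Gastric mucous and pancreatic genes were higher in the duodenum than in the jejunum. Stomach cells carried into the duodenal suspensions could raise other stomach genes too. The median difference of the other 1322 genes highest in the stomach was 0.015. Of them, 8 (0.61%) were called higher, against 83 of all 33833 genes. Both lists were left out of this set, so carried mucous cells alone were not tested. A small share of carried cells might also leave that median unmoved, so carriage stays open. A single pair of samples was argued against for the gastric mucous list, whose lowest array median over all its tested members was 0.93. For the pancreatic list the medians were 0.46, 0.45 and 0.22, above 0 on each array but too small to argue against a single pair. The list was called whichever sample was left out. Among genes well above background in all samples it was not (median -0.013), but Amy2a3 and Cpb1 fail that filter, which decides nothing. A difference between the 2 segments themselves stays open, and was not tested apart from the labels.

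The split that exchanged duodenum 3 and jejunum 2 called more genes than the labelled one, 2268 against 148, which points to a structure of the samples. If the channels of that array had been exchanged in the labels, the gastric mucous and duodenal uptake lists would be reversed on it, but their median over 29 genes was 0.44 there, against 0.48 and 0.41 on the other arrays. An unequal share of dividing crypt cells could contribute, since the cell proliferation list had a median of -0.38 on that array and 0.12 and 2.36 on the others, but the value of 0.12 leaves this open.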
